A study of Mus musculus with 4 samples.

How the data were processed

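RNA was measured from the first 2 cm of mouse colon after the caecum, at 6 weeks of age, in 4 libraries. The 2 control libraries carried one floxed allele of the transcription factor gene Nkx2-2 and no Cre, and the 2 mutant libraries carried 2 floxed alleles together with a Villin-Cre transgene, which drives recombination in the intestinal epithelium. The labels give the strain as mixed and say nothing on sex, litter, cage or sequencing batch. They do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries. Total RNA was extracted with a column kit and made into libraries with the TruSeq RNA kit, per the labels' protocols, which do not state how messenger RNA was selected. The submitters' processing notes name bcl2fastq 1.8.4, TopHat, Cufflinks and DESeq and the mouse build mm9, without further versions.

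Per the file headers, the authors gave each library a gene file of FPKM (fragments scaled by transcript length and by the mapped fragments of the library) with a 95% interval and a status for each of 23699 gene rows, and an isoform file of 30028 RefSeq transcripts. The isoform files also hold the coverage signal of each transcript, as deposited by the authors, and its length in bases. The authors' deposited table of the whole series holds DESeq results for 23284 genes. In it the authors gave the mean normalized count of each group (a signal, since no per-library counts are in it), the fold change as a ratio of mutant to control, its log2 value, a p-value and an adjusted p-value. Values from that table are named as such, and have no SD or n here. FPKM are not counts, so no count model was fitted, and the count tools planned in case the files held counts were not run.

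Rows with a status other than OK in at least 1 library were left out (306 of 23699 rows, of which 21 had a failed or too deep estimate and the rest too little data). This choice was made after the files were seen. Rows sharing a gene symbol were summed, which gave 23074 symbols. Genes with a mean of at least 0.5 FPKM over the 4 libraries (13997 genes) were tested as log2(FPKM + 0.5) with limma 3.58.1 (R 4.3.3), with a variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. The fit had 2 residual degrees of freedom, and a median of 6.27 prior degrees of freedom came from the other genes. Nkx2-2 lies under the 0.5 FPKM minimum, so its row was added to the same fit. Isoforms were tested in the same way. With 2 libraries against 2, the smallest p of an exact permutation test is 0.333, so none is given for single genes.

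There were 33 gene lists for cell types and programs, 5 of them for enteroendocrine cells, and 30 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01. camera asks whether a list's genes moved relative to all other genes. An estimated correlation and fry, which tests a list by itself, were run beside it. The design, the tests, the lists, the rule for named genes and all alternatives not called later additions were fixed before the data were examined. The rule names Nkx2-2, up to 10 genes in each direction past the threshold, the passing members and the 4 most abundant members of each enteroendocrine list, the 2 members with the smallest p of each other list without a passing member (4 where one passes), and up to 5 genes in each direction past the threshold in the authors' deposited table. Some genes that the rule names are not reported here. Other genes are said to be chosen after their values were seen. Alternatives covered the pseudocount, the filter, the scaling between libraries, the variance model, summing of rows, the replicate number as a term, each library left out in turn, and the authors' deposited table. Later additions were all rows kept whatever their status, and the removal of small RNA, RNA component and histone genes with the rest rescaled to an equal total.

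Depth is not stated in the files. The width of a 95% FPKM interval gives the number of fragments behind it, and in genes with 1 isoform and under 50 fragments, 86.9% of the implied numbers in control 1 and 87.8% in mutant 1 lay within 0.05 of a whole number. The ratio of coverage to FPKM, which rises with depth, put mutant 1 at 0.464 of control 1. Low values in mutant 1 therefore rest on fewer fragments. Intervals and implied fragments cover counting error only.

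Coordinates are on mm9, as in the files, written from 1. Exons and coding parts come from GENCODE vM1 on the same assembly. The fit and camera were tested on simulated data for the comparison of mutant with control over 13997 genes, of which 200 were changed. Of the 50 genes per fold size, 28% were recovered at 2-fold, 90% at 4-fold, 100% at 8-fold and 100% at 16-fold, with 4 false calls among unchanged genes. The 1 shifted list of 30 was recovered and 0 of the others were called. Simulated genes varied independently, with normal noise whose variances were drawn from the fitted model, so the data met the assumptions of the test. The spread was the same in all libraries, with no difference in depth or scaling between them. camera was run there at the preset correlation only. These rates therefore do not cover correlated genes, departures from the model, the lower depth of mutant 1 or the choice of scaling. They also do not cover an estimated correlation or fry. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).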

Results

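The data comprised 4 RNA-seq libraries of proximal colon from 6-week-old mice, 2 from controls with one floxed Nkx2-2 allele and 2 from mutants in which Villin-Cre acts on both floxed alleles in the gut epithelium. Nkx2-2 is a homeodomain transcription factor of the enteroendocrine lineage, the hormone-secreting cells scattered through the epithelium. Sequencing depth relative to control 1 was 1.13 in control 2, 0.464 in mutant 1 and 1.03 in mutant 2. Across 13997 tested genes, Pearson correlations of log2 values between libraries ran from 0.965 (control 1 with mutant 1) to 0.984 (control 2 with mutant 2), and genes are not independent replicates. The controls correlated at 0.977 and the mutants at 0.975. All 4 libraries expressed the X-inactivation transcript Xist, at 44.5 to 58.0 FPKM.

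The first comparison asked how much Nkx2-2 RNA remained. Nkx2-2 stood at 0.724 and 0.609 FPKM in the control libraries (0.667 ± 0.0808, SD, n = 2) and at 0.125 and 0.351 FPKM in the mutant libraries (0.238 ± 0.160, SD, n = 2). Both mutant values lay below both control values. The log2 change was −0.68 (SE 0.32, 95% interval −1.40 to 0.05). This difference did not pass (limma adjusted p = 0.825, unadjusted 0.0635). The values rest on 16.4 and 15.4 implied fragments in the controls, 1 in mutant 1 and 4.7 in mutant 2. In mutant 1, olfactory receptor genes, which the colon is not known to use broadly, averaged 0.125 FPKM. The log2 change was −0.90 without mutant 2 (unadjusted p = 0.0321), −0.45 without mutant 1 (0.177), −0.60 without control 1 (0.153) and −0.75 without control 2 (0.0901). It was −1.26 with a pseudocount of 0.1 (unadjusted p = 0.0711) and −0.43 with a pseudocount of 1 (0.0672).

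Nkx2-2 lies on the minus strand of chromosome 2, from 147003282 to 147012138 on mm9, and the files hold 2 RefSeq isoforms of it. NM_010919 spans 147008888 to 147012138 with a length of 2049 bases, and NM_001077632 spans 147003282 to 147012138 with a length of 1354 bases. Both start in exon 1 (147011496 to 147012138), and NM_010919 alone holds the stretch of exon 2 from 147008888 to 147009981, which is 1094 bases long. GENCODE places the end of the coding sequence, from 147009734 of exon 2, and the 3′ UTR in that stretch. In the control libraries the whole estimate fell on NM_010919, at 0.724 and 0.609 FPKM, and NM_001077632 was listed at 0. In the mutant libraries NM_010919 was listed at 0 and the estimate fell on NM_001077632, at 0.125 FPKM in mutant 1 (interval 0 to 0.375) and 0.351 FPKM in mutant 2 (interval 0.0334 to 0.670). The labels do not say which exons the floxed allele removes, and these low isoform values had no test of their own.

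The central comparison asked which genes differed between mutant and control colon. In the mutants, Tph1, which encodes the rate-limiting enzyme of serotonin synthesis in the gut, fell from 17.1 ± 2.39 to 0.875 ± 0.737 FPKM (SD, n = 2 each), a 13.8-fold lower level on the log2(FPKM + 0.5) scale. The granins Chga and Chgb, proteins of hormone granules, fell from 56.6 ± 18.7 to 6.78 ± 2.70 FPKM and from 83.3 ± 20.5 to 7.50 ± 5.08 FPKM. Insl5, a peptide hormone of colonic enteroendocrine cells, fell from 6.74 ± 0.632 to 0.790 ± 0.159 FPKM. Ghrl, which encodes the hormone ghrelin, rose from 2.16 ± 0.0940 to 13.1 ± 3.19 FPKM, a 5.04-fold higher level. Of 13997 genes, 9 passed, 5 higher and 4 lower in the mutants.

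The 4 genes that fell had log2 changes of −3.79 for Tph1 (SE 0.36), −2.98 for Chga (SE 0.31), −3.53 for Chgb (SE 0.41) and −2.49 for Insl5 (SE 0.24). Ghrl had a log2 change of 2.33 (SE 0.24). Their limma adjusted p-values were 0.0140 for Tph1, 0.0163 for Chga, 0.0302 for Chgb, 0.0140 for Insl5 and 0.0163 for Ghrl, and in each the mutant libraries lay outside the range of the controls. The lowest values had few implied fragments, with 2.4 in mutant 1 for Tph1 and 3 for Insl5. On mm9 these genes lie at 53902501 to 53927907 of chromosome 7 (Tph1), 103793179 to 103803237 of chromosome 12 (Chga), 132607014 to 132620808 of chromosome 2 (Chgb), 102690478 to 102699333 of chromosome 4 (Insl5) and 113666113 to 113669874 of chromosome 6 (Ghrl).

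The other 4 genes that passed encode short RNAs. Rmrp and Rpph1, the RNA components of the RNase MRP and RNase P enzymes, rose from 34.6 ± 2.95 to 274.3 ± 63.7 FPKM (log2 change 2.95, SE 0.21, adjusted p = 0.00185) and from 7.93 ± 4.08 to 66.9 ± 11.5 FPKM (log2 change 3.08, SE 0.32, adjusted p = 0.0163). The small nucleolar RNA gene Snord15b stood at 135.3 and 194.8 FPKM in the mutants, from 5 and 16 implied fragments, and was listed at 0 in both controls. The microRNA gene Mir1199 stood at 89.1 and 40.1 FPKM, from 1 implied fragment in each mutant, and was also listed at 0 in both controls. The authors' deposited table has mean normalized counts of 0.397 in controls and 12.2 in mutants for Snord15b and 0.768 and 6.00 for Mir1199, each with an adjusted p of 1. In the same libraries 36 of 61 tested histone genes of the clustered kind, whose messages mostly lack a poly(A) tail, were higher in both mutants than in both controls, against 16.7% by chance and 3.39% of all tested genes.

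The median log2 change of all tested genes was −0.17 as deposited and 0.01 after median ratio rescaling. As deposited, 82.6% of tested genes had a change below 0, which is the background for the counts of lower and higher genes given for each list. Relative to that median, the changes were −3.62 for Tph1, −2.81 for Chga, −3.36 for Chgb, −2.32 for Insl5 and 2.50 for Ghrl. At an unadjusted p under 0.05, 98 genes were higher and 577 lower as deposited, against 209 higher and 256 lower after rescaling. In limma, the number of genes past the threshold was 3 after rescaling (3 higher, 0 lower), 2 after quantile normalization (2 higher, 0 lower), 2 with no filter and 0 by limma with small RNA and histone genes left out (111 higher and 365 lower at an unadjusted p under 0.05). The adjusted p after rescaling was 0.193 for Tph1, 0.219 for Chga, 0.349 for Chgb, 0.193 for Insl5 and 0.210 for Ghrl, with log2 changes of −3.66, −2.81, −3.35, −2.34 and 2.50. Each of these genes lost its call without mutant 1, with log2 changes of −3.21, −2.59, −2.83, −2.62 and 2.09 in the same order. Chga, Insl5 and Ghrl also lost it without mutant 2, where the log2 changes were −4.36, −3.37, −4.23, −2.36 and 2.57. The number of genes was 124 without control 1, 362 without control 2, 8 without mutant 1 and 12 without mutant 2, and these shared 9, 9, 3 and 5 genes with the 9.

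**Figure D1:**
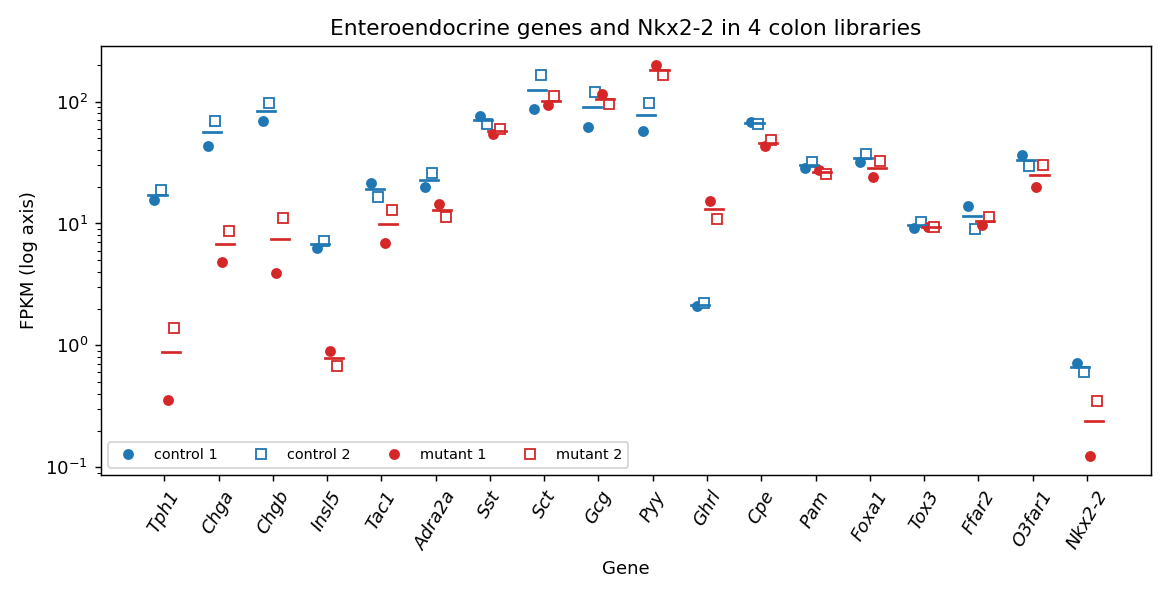
FPKM on a log axis of 17 enteroendocrine genes and Nkx2-2 in the 4 libraries, with a point per library and a short line at each group mean of 2 libraries. Tph1, Chga, Chgb and Insl5 lie lower and Ghrl higher in both mutants, while Gcg, Sct and Ffar2 overlap between groups.

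Of 110 genes on the 5 enteroendocrine lists, 78 were tested and 5 passed over all genes, 4 lower and 1 higher. Adjusted over the list alone, 12 passed, 10 lower and 2 higher. The 2 higher were Ghrl and Pyy, and the 10 lower were Tph1, Insl5, Chga, Chgb, Adra2a, Resp18, Pcsk1n, Foxa2, Amigo2 and Npy, of which Resp18, Pcsk1n, Foxa2, Amigo2 and Npy were chosen after their values were seen. No member passed over all genes after median ratio rescaling or quantile normalization, and 6 passed over the list alone under each. Without mutant 1, 0 passed over all genes and 6 over the list alone.

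Among the 12 tested genes of the enterochromaffin list, which covers the serotonin cells, 9 were lower and 3 higher, and Tph1, Chga and Chgb passed. Tac1, the precursor of substance P, had 19.1 ± 3.61 FPKM in controls and 9.95 ± 4.26 FPKM in mutants, and the adrenergic receptor gene Adra2a 22.9 ± 4.20 and 12.8 ± 2.18 FPKM, with limma adjusted p-values of 0.825 over all genes for each. Lmx1a, a transcription factor of serotonin cells named after its values were seen, was below the filter at 0.488 and 0.451 FPKM in controls and 0.320 and 0.0823 FPKM in mutants. As a list it was lower by camera (median −0.48 relative to all genes, adjusted p = 0.000130). That call was lost by camera with an estimated correlation (adjusted p = 0.632) and without mutant 2. With each library left out in turn, the list median ran from −0.56 without control 1 to −0.29 without mutant 2.

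Hormones of the other enteroendocrine cells went both ways. Of the 12 tested peptide hormone genes 4 were higher and 8 lower, and Ghrl and Insl5 passed over all genes. Pyy, the peptide YY gene, had 76.9 ± 27.9 FPKM in controls and 181.7 ± 22.6 FPKM in mutants (log2 change 1.28, SE 0.25, limma adjusted p = 0.404 over all genes and 0.0120 over the enteroendocrine lists). Gcg, the glucagon-like peptide gene, had 90.6 ± 40.7 and 105.7 ± 15.1 FPKM, with a 95% interval of the log2 change from −0.38 to 0.96. The secretin gene Sct had 125.0 ± 54.4 and 101.9 ± 11.96 FPKM (interval −0.88 to 0.42), and the somatostatin gene Sst 70.3 ± 7.70 and 57.2 ± 3.89 FPKM (interval −0.71 to 0.12). The list as a whole did not pass (camera adjusted p = 0.368), and its median relative to all genes was −0.09 while the test pointed up. Without control 1 it was lower (median −0.40, adjusted p = 0.0306).

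The secretory granule list had 28 tested genes, 26 lower and 2 higher, and only the granins Chga and Chgb passed over all genes. Cpe, a carboxypeptidase that trims prohormones, had 66.4 ± 2.04 FPKM in controls and 45.8 ± 3.31 FPKM in mutants (limma adjusted p = 0.825), and the amidating enzyme gene Pam had 30.2 ± 2.63 and 26.4 ± 1.20 FPKM. The list was lower by camera (median −0.35 relative to all genes, adjusted p = 1.53e-06) and was the 1 called list that passed with each of the 4 libraries left out in turn. Its adjusted p = 0.632 with an estimated correlation. The enteric neuron list, which shares Snap25 with it, was also lower by camera (adjusted p = 0.0182), so the granule call does not single out enteroendocrine cells.

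None of the 19 tested genes of the endocrine transcription factor list passed over all genes, with 7 higher and 12 lower and 1 at an unadjusted p under 0.05 in limma. Foxa1 had 34.3 ± 3.65 FPKM in controls and 28.4 ± 6.20 FPKM in mutants, Tox3 9.78 ± 0.836 and 9.36 ± 0.101 FPKM, and the stimulus-induced factor Egr1 8.95 ± 1.12 and 6.80 ± 2.27 FPKM. The receptors for nutrients gave 0 passing genes of 10 tested, 4 higher and 6 lower, with 0 at an unadjusted p under 0.05 in limma. The short-chain fatty acid receptor gene Ffar2 had 11.4 ± 3.55 and 10.5 ± 1.09 FPKM, and the long-chain fatty acid receptor gene O3far1 33.1 ± 4.69 and 24.9 ± 7.18 FPKM. Abcc8, a subunit of the ATP-sensitive potassium channel, and Agr3 stayed under 2.01 FPKM in every library. Neither list passed by camera (adjusted p = 0.242 and 0.706).

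Other cell types and programs were compared through 28 further lists, of which 25 had enough tested genes. By camera 5 lists of the 30 tested were higher and 10 lower, relative to all genes, against 3 higher and 11 lower after median ratio rescaling, with 13 lists shared. With an estimated correlation 0 of the 30 passed (smallest adjusted p = 0.632, 0 at an unadjusted p under 0.05), and by fry 0 passed (smallest adjusted p = 0.162, 3 at an unadjusted p under 0.05). None of the single genes named from these 28 lists passed over all genes in limma, so their values are given as FPKM. Counts of lower genes are also high in lists that did not pass, with 17 of 19 fibroblast, 15 of 18 stem, 8 of 9 adipocyte and 13 of 16 goblet genes, against 82.6% of all tested genes.

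Of the immune lists, the T and NK cell, myeloid and MHC class II lists were lower by camera. All 17 tested T and NK cell genes had negative changes (median −0.57 relative to all genes, camera adjusted p = 1.53e-06, 0.632 with an estimated correlation), with the chemokine gene Ccl5 at 126.2 ± 39.2 FPKM in controls and 55.5 ± 11.7 FPKM in mutants and Cd7 at 14.5 ± 0.992 and 8.36 ± 0.130 FPKM. All 18 myeloid genes had negative changes (median −0.24, camera adjusted p = 0.0196, 0.802 with an estimated correlation), among them the neutrophil genes S100a8 at 6.57, 1.29, 0 and 1.77 FPKM and S100a9 at 1.91, 1.06, 0 and 0.926 FPKM in control 1, control 2, mutant 1 and mutant 2. The MHC class II list was lower (median −0.35, camera adjusted p = 0.0196, 0.733 with an estimated correlation), with H2-DMb2 at 61.1 ± 3.60 FPKM in controls and 29.8 ± 1.79 FPKM in mutants and H2-Oa at 3.92 ± 2.96 and 0.984 ± 0.669 FPKM. The class II call rested on mutant 1, and without it the list median was 0.07 relative to all genes (adjusted p = 0.616). The T and NK call was lost without control 1 (median −0.23) and without mutant 2 (−0.52), and the median was −0.87 without control 2. The myeloid call was lost without control 1 (median −0.04) and without mutant 1 (−0.02). The myeloid median was −0.37 without control 2 and −0.41 without mutant 2.

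Control 1 stood apart in B cell genes. The B and plasma cell list did not pass (camera adjusted p = 0.0523, median −0.87 relative to all genes) but was lower by camera after median ratio rescaling (adjusted p = 0.00812). Without control 2, which leaves control 1 as the lone control, its median was −2.25 relative to all genes. Pax5, the transcription factor of B cells, had 4.19 FPKM in control 1 and 0.0589, 0.143 and 0 FPKM in control 2, mutant 1 and mutant 2. The B cell receptor-like gene Fcrla had 9.84 FPKM in control 1 and 1.18, 1.29 and 1.11 FPKM in the others. Without control 1 the list median was 0.47 relative to all genes, so its direction turned with the control that was left out.

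Of the lists of the gut wall and its vessels, enteric glia, enteric neurons, interstitial cells of Cajal, endothelium and blood were lower by camera, and smooth muscle and fibroblasts did not pass. All 9 tested genes of enteric glia had negative changes (median −0.37 relative to all genes, camera adjusted p = 0.00103, 0.632 with an estimated correlation), with the glial filament gene Gfap at 2.59 ± 0.467 FPKM in controls and 1.49 ± 0.0684 FPKM in mutants and Gpr37l1 at 2.76 ± 0.0451 and 1.45 ± 0.267 FPKM. Of 22 enteric neuron genes 20 were lower (median −0.25, camera adjusted p = 0.0182, 0.733 with an estimated correlation), with the synaptic gene Snap25, also a member of the granule list, at 5.38 ± 0.627 and 2.84 ± 1.37 FPKM and Phox2a at 1.20 ± 0.686 and 0.286 ± 0.116 FPKM. Interstitial cells of Cajal, the pacemaker cells, had 7 lower genes of 7 (median −0.20, adjusted p = 0.0279, 0.674 with an estimated correlation), among them Ano1 at 12.6 ± 1.29 and 9.63 ± 0.799 FPKM and Prkcq at 2.28 ± 0.550 and 1.20 ± 0.713 FPKM. Endothelial genes were lower in 14 of 15 (median −0.17, adjusted p = 0.0437, 0.632 with an estimated correlation), with Tie1 at 3.13 ± 0.213 and 1.78 ± 0.0376 FPKM and Cldn5 at 5.91 ± 0.979 and 3.73 ± 0.914 FPKM. Of 5 blood genes 4 were lower (median −1.73, adjusted p = 0.0437, 0.632 with an estimated correlation), with the near-identical hemoglobin genes Hba-a1 at 73.6 ± 23.3 and 32.0 ± 3.01 FPKM and Hba-a2 at 29.4 ± 16.3 and 8.54 ± 12.1 FPKM, between which reads cannot be split with certainty. The Cajal cell call was lost with each library left out in turn, and the endothelial call in every such fit but that without mutant 1. The neuron, glia and blood calls were each lost with at least 1 library left out. Over these fits the neuron median ran from −0.36 to −0.05 relative to all genes and the glia median from −0.47 to −0.26. Cajal cell medians ran from −0.33 to −0.17, endothelial from −0.22 to −0.13 and blood from −1.69 to −0.58. Smooth muscle (adjusted p = 0.169) and fibroblast genes (0.706) did not pass, with Myh11 at 129.3 ± 8.56 and 99.3 ± 12.01 FPKM, Ckm at 14.8 ± 1.48 and 9.78 ± 2.25 FPKM, Dcn at 176.1 ± 24.8 and 125.0 ± 16.1 FPKM and Thy1 at 19.9 ± 7.34 and 12 ± 3.19 FPKM. Fibroblast genes had a median 0.02 above all genes while the test pointed down.

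Of the epithelial lists other than the endocrine ones, proliferation and small intestinal genes passed. Goblet genes had a camera adjusted p of 0.222, with the mucosal peptide gene Tff3 at 2152.2 ± 93.7 FPKM in controls and 1622.0 ± 38.4 FPKM in mutants and Tpsg1 at 53.6 ± 1.09 and 36.6 ± 4.41 FPKM. Absorptive colonocyte genes had an adjusted p of 0.0607, with the water channel gene Aqp4 at 37.4 ± 8.08 and 53.0 ± 8.55 FPKM and Slc37a2 at 35.8 ± 20.3 and 10.8 ± 6.41 FPKM. Tuft cell genes (adjusted p = 0.706) included Cd24a at 404.2 ± 58.7 and 280.5 ± 59.0 FPKM and Hpgds at 3.71 ± 0.0544 and 2.66 ± 0.368 FPKM. Stem and crypt genes (0.706) included Axin2 at 10.4 ± 1.68 and 7.54 ± 0.528 FPKM and Sox9 at 12.7 ± 1.43 and 9.94 ± 1.68 FPKM. Of the Paneth and antimicrobial list (0.573), the lectin gene Reg4, also known from enteroendocrine cells, had 358.8 ± 89.2 and 145.2 ± 30.3 FPKM (limma adjusted p = 0.287) and the protease gene Mmp7 56.2 ± 16.6 and 30.5 ± 1.68 FPKM. Proliferation genes were higher by camera relative to all genes (median 0.13 relative, −0.03 as fitted, adjusted p = 0.0251, 0.811 with an estimated correlation), with Ccnb2 at 41.1 ± 5.03 and 33.4 ± 8.82 FPKM and Plk1 at 28.1 ± 0.230 and 25.2 ± 7.43 FPKM, and the list turned lower without mutant 2 (median −0.05, adjusted p = 0.233). The proliferation call was also lost without control 1 (0.0637) and without control 2 (0.637). Small intestinal enterocyte genes were higher (median 0.20 relative to all genes, mean −0.08 as fitted, camera adjusted p = 0.00825, 0.733 with an estimated correlation), with Fabp6 at 47.6 ± 7.90 and 59.9 ± 4.44 FPKM and Apoa4 at 0.137 and 5.33 FPKM in the controls and 0.0981 and 0.0442 FPKM in the mutants. Without control 1 this list was lower (median −0.12, adjusted p = 3.53e-05), and its call was lost without mutant 1 (median −0.03, adjusted p = 0.878).

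Of the programs, cholesterol synthesis was higher by camera as a list, with 15 of 19 genes above 0 and 0 at an unadjusted p under 0.05 in limma (median 0.35 relative to all genes, adjusted p = 4.02e-06, 0.733 with an estimated correlation). Without control 1 the list median was −0.04 (adjusted p = 0.673), and the call was also lost without mutant 2 (0.0875). Interferon genes were higher relative to all genes in the same test (median 0.22, adjusted p = 2.16e-05, 0.632 with an estimated correlation). Isg15 had 94.1 ± 19.3 FPKM in controls and 109.5 ± 6.78 FPKM in mutants, and Oas2 5.77 ± 1.35 and 8.24 ± 0.677 FPKM. The interferon median ran from 0.08 without control 1 to 0.39 without control 2, and the call was lost without control 1 and without mutant 2. The circadian list was higher (median 0.16 relative, −0.01 as fitted, adjusted p = 0.0180, 0.632 with an estimated correlation), with Per2 at 2.03 ± 0.532 and 3.33 ± 0.263 FPKM and Npas2 at 7.47 ± 2.96 and 4.91 ± 0.485 FPKM, and its median was −0.16 without control 1 (adjusted p = 0.272). The circadian call was also lost without mutant 1 (0.0840) and without mutant 2 (0.0641). After median ratio rescaling the small intestinal (adjusted p = 0.137) and circadian (0.176) calls were lost. Immediate early genes (0.488), with Btg2 at 39.1 ± 1.05 and 27.2 ± 3.06 FPKM and Nr4a1 at 4.66 ± 0.633 and 2.83 ± 0.699 FPKM, and colon region genes (0.0914), with Cdx2 at 196.7 ± 16.8 and 165.6 ± 19.6 FPKM and Hoxd11 at 1.45 ± 1.11 and 1.78 ± 0.0122 FPKM, did not pass. Genes of serotonin uptake, breakdown and receptors (0.706), with Aldh2 at 144.3 ± 5.19 and 112.5 ± 4.26 FPKM and Sult1a1 at 296.1 ± 113.6 and 212.6 ± 36.5 FPKM, and adipocyte genes (0.706), with Pparg at 99.5 ± 21.9 and 73.8 ± 3.40 FPKM and Plin4 at 3.23 ± 0.206 and 2.61 ± 0.255 FPKM, did not pass either. The mast cell, pancreas and sex-linked lists had 4, 3 and 1 tested genes and were not tested as lists. Their median log2 changes were −0.41, −0.26 and 0.01, with Kit at 18.9 ± 3.96 and 15.5 ± 1.49 FPKM, Cpa3 at 0.667 ± 0.341 and 0.397 ± 0.415 FPKM, Clps at 20.7 ± 5.84 and 11.9 ± 1.14 FPKM and Cela1 at 31.4 ± 3.27 and 26.3 ± 5.37 FPKM.

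**Figure D2:**
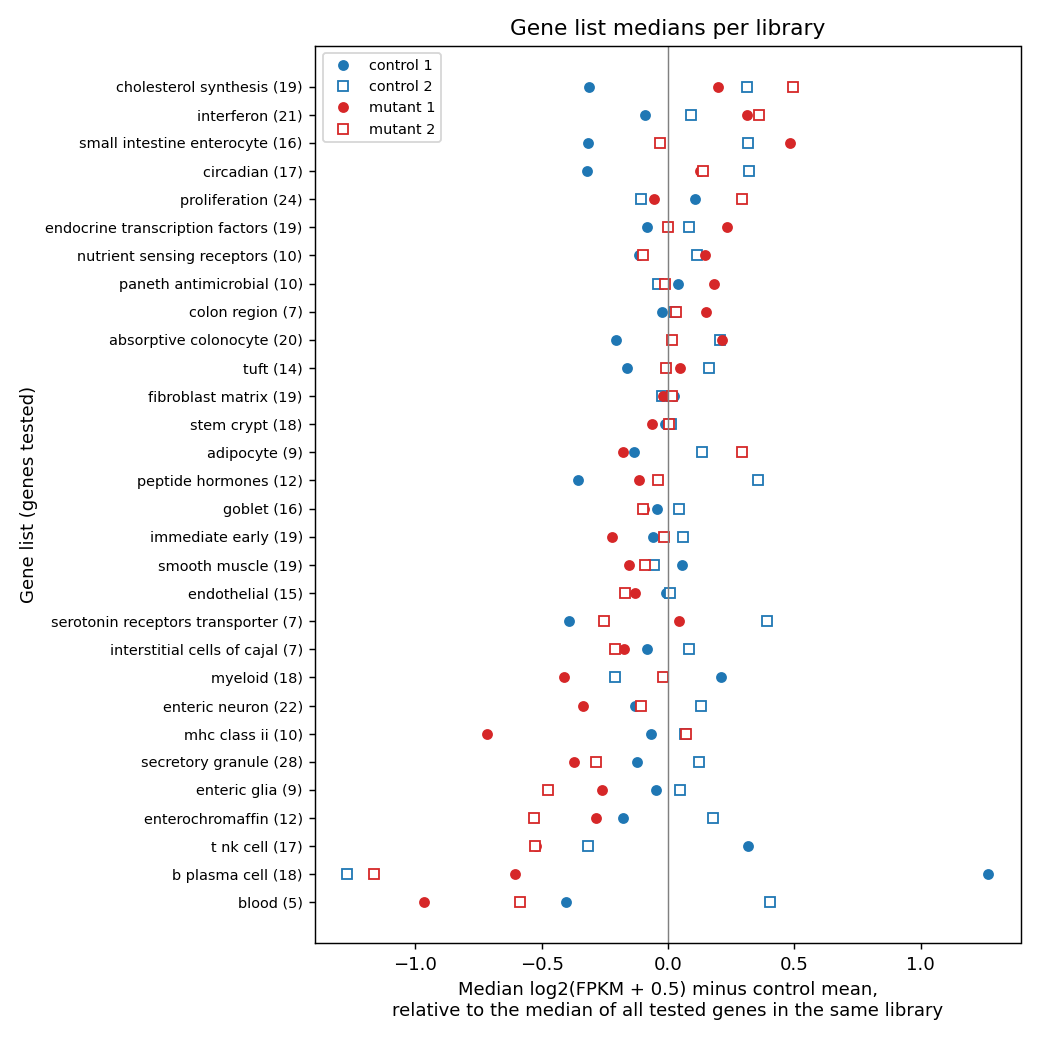
Median of each tested gene list in each library, as log2(FPKM + 0.5) minus the control mean and relative to the median of all tested genes in that library, with a point per library. The secretory granule, enteric glia and enterochromaffin medians lie lower in both mutants than in both controls. So do the T and NK cell, blood, Cajal cell, endothelial, smooth muscle and goblet medians. The B and plasma cell median is high in control 1 alone.

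The authors' deposited table compared the same groups with DESeq on counts. In it 8 genes had an adjusted p under 0.05, with Mt1, Rmrp, Pnp2 and Rpph1 higher and Tph1, Ahcy, Chgb and Gsdmc4 lower in mutants. Of these, Tph1, Chgb, Rmrp and Rpph1 were the 4 genes shared with the FPKM test. In the authors' deposited table Tph1 had a mean normalized count of 339.6 in controls and 21.6 in mutants (log2 fold change −3.98, adjusted p = 3.53e-11), and Chgb 2595.8 and 252.3 (−3.36, adjusted p = 0.00326). Chga had a log2 fold change of −2.94 there with an adjusted p of 0.524, and Insl5 (−3.01), Ghrl (2.79), Pyy (1.39) and Nkx2-2 (−0.89) had an adjusted p of 1 in the authors' deposited table. Across 13892 genes, the authors' log2 fold changes and those from FPKM correlated at Pearson's r of 0.788 and Spearman's rho of 0.935, and genes are not independent replicates.

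Mt1, a metallothionein that binds zinc and copper, had 233.6 ± 24.9 FPKM in controls and 586.7 ± 58.5 FPKM in mutants, a log2 change of 1.33 (SE 0.17) that missed the threshold in limma (adjusted p = 0.0693), with both mutants above both controls. In the authors' deposited table its log2 fold change was 1.56 (adjusted p = 1.34e-12). Gsdmc4, of the gasdermin C family, had 268.5 ± 21.0 and 135.0 ± 16.8 FPKM (log2 change −0.99, SE 0.18, limma adjusted p = 0.287), against −0.88 in the authors' deposited table (adjusted p = 0.0117). Ahcy had 60.6 ± 0.312 and 46.8 ± 1.06 FPKM, a log2 change of −0.37 (SE 0.17), against −2.23 in the authors' deposited table (adjusted p = 0.00214). Pnp2 had 12.1 ± 2.08 and 20.9 ± 5.16 FPKM, a log2 change of 0.75 (SE 0.24), against 5.35 in the authors' deposited table (adjusted p = 3.61e-06). The 95% intervals from FPKM, −0.76 to 0.02 for Ahcy and 0.21 to 1.29 for Pnp2, exclude these larger values. Set against the implied fragments of the controls, the authors' control count was 11.1% for Ahcy and 1.38% for Pnp2, against a median of 77.8% over 12391 genes. Both values are therefore uncertain, as for genes whose reads can be shared with near-identical copies.

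At the level of isoforms, 16903 of 30028 transcripts were tested and 1 passed, NR_002173 of Snord15b (limma adjusted p = 0.00694), with 708 at an unadjusted p under 0.05. No isoform of Tph1, Chga, Chgb, Insl5 or Ghrl passed on its own in this fit.

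**Figure D3:**
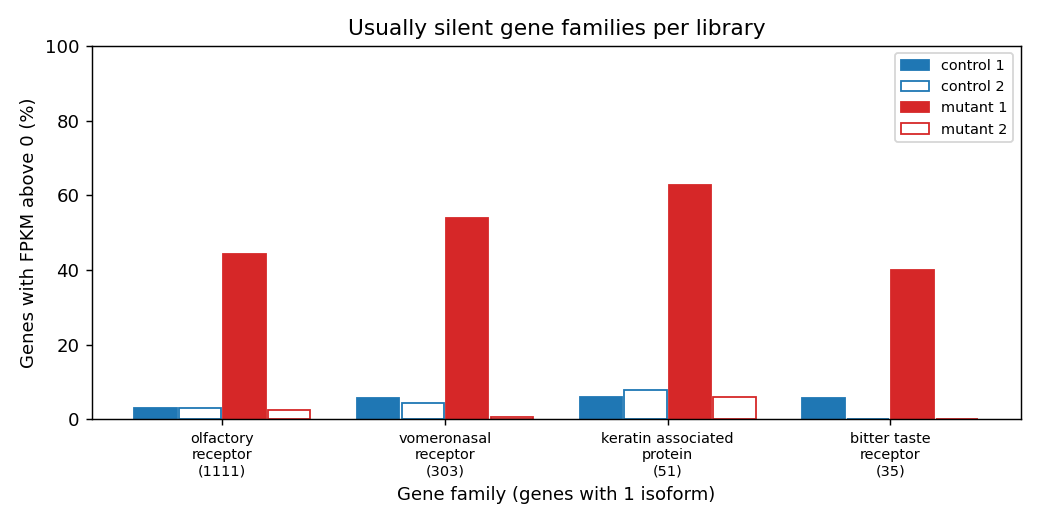
Percent of genes with FPKM above 0 in 4 gene families that most tissues do not use, per library, over genes with 1 isoform, on a linear axis from 0 to 100%. Mutant 1 lies at 40 to 62.7% in the 4 families, and the other 3 libraries lie at 0 to 7.84%.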

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

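All tests of explanations in this part were chosen only after the result was seen.

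The ribosomal RNA precursor Rn45s lies outside the gene test because its status was not OK in mutant 1, and it was picked out as a signal above the controls in data left out of the comparison. It stood at 2791.1 and 2375.9 FPKM in the controls and 8893.4 FPKM in mutant 2, and mutant 1 has a value of 0 with the status for too deep data. In the authors' deposited table Rn45s took 1.32% of the control counts and 11.9% of the mutant counts, with an adjusted p of 1, and that table does not split the share by library. It goes together with the higher histone genes (median 0.80 relative to all genes) and RNA components Rmrp and Rpph1. The histone median was 1.08 in mutant 1 and 0.43 in mutant 2, relative to all genes. The 25 tested small nucleolar and Cajal body RNA genes had unlike medians in the mutants. Their median change against the control mean, here not relative to all genes, was 0 in mutant 1 and 2.21 in mutant 2. It was also 0 in each control. Mutant 1 had 0.464 of the depth of control 1, so a rise there could have been missed. Of these 25 genes 28% were higher in both mutants than in both controls, against 3.39% of all tested genes. More dividing cells are argued against in mutant 1, where the upper quartile of the proliferation list was 0.070 and the lower quartile of the histone genes 0.61 relative to all genes. In mutant 2 the proliferation list had a median of 0.29 and an upper quartile of 0.37 against histone quartiles of −0.026 and 1.06, and more dividing cells and RNA without a poly(A) tail cannot be told apart for its histone genes, since these ranges overlap. An overstatement of short transcripts by FPKM is also argued against for the histone genes, Rmrp and Rpph1. Together these had a median of 1.59 relative to all genes in the authors' deposited table. It stays open whether more RNA without a poly(A) tail went into the mutant libraries. The 11.9% of counts on Rn45s is the flagged result itself and is pooled over the mutants, so it is no test of this. With 2 libraries per group, such a difference would be confounded with genotype.

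Olfactory receptor genes were picked out because 44.2% of 1111 genes had a value above 0 in mutant 1, against 2.97% in each control and 2.52% in mutant 2. Vomeronasal receptor, keratin associated protein and bitter taste receptor genes stood above 0 in 53.8%, 62.7% and 40% of genes in mutant 1. Deeper sequencing is argued against, since mutant 1 had 0.464 of the depth of control 1, and an effect of the genotype alone is argued against by the 2.52% in mutant 2. Fragments in mutant 1 were spread over olfactory receptor genes with a variance 1.43 times that of even scatter, against 9.996 in control 1. A few expressed receptors can raise a control ratio. The highest value in control 2 was that of Olfr558 (1.13 FPKM), a member of the nutrient receptor list. The contrast by itself therefore does not show a different kind of scatter. In vomeronasal receptor genes the ratio was 1.39 in mutant 1 and 1.42 in control 1, so the spread alone did not set mutant 1 apart there. The values above 0 in mutant 1 may be stray fragments spread over the genome, such as from genomic DNA. Low values in mutant 1, among them the 0.125 FPKM of Nkx2-2, could hold some of these fragments.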

How the results depend on the processing

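The alternatives here that were chosen after the data were seen are rows of any status kept and small RNA and histone genes left out. The 9 called genes kept their direction under every alternative that gave a value, and of 140 such results 99 kept their call and 41 lost it. For all moved or reversed values below, the cause was not tested. Their log2 changes ran from −4.38 to −3.21 for Tph1, −3.37 to −2.59 for Chga, −4.23 to −2.83 for Chgb, −2.95 to −2.11 for Insl5 and 2.09 to 2.57 for Ghrl. The adjusted p ran from 3.45e-31 to 0.442 for Tph1, 6.37e-26 to 0.619 for Chga, 5.38e-38 to 0.797 for Chgb, 2.94e-12 to 0.33 for Insl5 and 5.23e-12 to 0.521 for Ghrl. The depth of mutant 1 limits low genes, and 28% of simulated 2-fold changes were recovered. The count tools planned for counts were not run, since the files hold none per library. With the replicate number as a term (replicate block, correlation of same-numbered libraries −0.00217), 195 genes, 12 enteroendocrine genes and 2 isoforms passed, Nkx2-2 had −0.68 (unadjusted p = 0.0497), and the Paneth and adipocyte lists turned lower by test, at 0.10 and −0.053. The labels do not state that the number pairs the libraries.

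List values are medians relative to all genes, and a list is named where the direction of its test turned. With no filter, 2 genes, 0 enteroendocrine genes (5 over the list alone) and 0 isoforms passed in limma (145 genes higher and 506 lower at an unadjusted p under 0.05), and Nkx2-2 had −0.68 (unadjusted p = 0.0339). The tuft list was then at −0.00086, Paneth −0.087, adipocyte −0.097 and serotonin receptors 0.24. With a minimum of 1 FPKM tuft was at 0.022 and adipocyte at −0.073. After median ratio rescaling 3 genes and 0 enteroendocrine genes (6 over the list alone) passed, with Ffar2 at 0.089, Tox3 0.12, and the lists peptide hormones −0.081, nutrient receptors 0.088, tuft 0.024, Paneth 0.10, fibroblast 0.034 and adipocyte −0.11. After quantile normalization 2 genes and 0 enteroendocrine genes (6 over the list alone) passed, with Ffar2 at 0.096, Tox3 0.13, peptide hormones −0.12, nutrient receptors 0.10, Paneth −0.059 and adipocyte −0.059. With no trend 3 enteroendocrine genes (6 over the list alone) and 0 isoforms passed, and Nkx2-2 had −0.68 (unadjusted p = 0.0202). A robust trend gave 3 enteroendocrine genes, each row on its own 6 over the list alone, and rows of any status kept 6 over the list alone. With small RNA and histone genes left out, 0 genes and 0 enteroendocrine genes (6 over the list alone) passed in limma (111 higher and 365 lower at an unadjusted p under 0.05), with Ffar2 at 0.026 and Tox3 0.058. Of the enteroendocrine genes 2 passed in the authors' table. By an estimated correlation 0 gene lists passed and by fry 0 passed (0 and 3 at an unadjusted p under 0.05).

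With each library left out in turn (leave-one-out, a lone library being assumed to vary like the other group), the number of genes ran from 8 to 362, enteroendocrine genes 0 to 10 (6 to 14 over the list alone), lists 6 to 12 and isoforms 0 to 0. Nkx2-2 ran from −0.90 to −0.45. Among named genes, Abcc8 ran from −0.0796 to 0.40, Arntl −0.93 to 0.34, Cpa3 −0.92 to 0.0598, Dbp −0.92 to 1.30, Fcrla −2.61 to 0.017, Ffar2 −0.40 to 0.22, Gcg −0.18 to 0.76, Hoxd11 −0.27 to 0.97, Ms4a1 −3.63 to 0.47, Pax5 −3.05 to 0.021, Plk1 −0.49 to 0.11, Sct −0.68 to 0.23, Tox3 −0.14 to 0.026 and Xist −0.18 to 0.20. Among lists, absorptive genes ran from −0.10 to 0.30, adipocyte −0.18 to 0.29, B and plasma cell −2.25 to 0.47, cholesterol −0.037 to 0.65, circadian −0.16 to 0.48, endocrine transcription factors −0.0012 to 0.23, fibroblast −0.0198 to 0.017, immediate early −0.22 to −0.014, MHC class II −0.72 to 0.072, nutrient receptors −0.10 to 0.15, Paneth −0.0102 to 0.18, peptide hormones −0.40 to 0.12, proliferation −0.054 to 0.29, serotonin receptors −0.32 to 0.17, small intestine −0.12 to 0.49, stem −0.10 to 0.0025 and tuft −0.071 to 0.17. Over all alternatives, and not only those with a library left out, 378 list results kept direction and call. Another 17 gained the call, 41 lost it and 43 turned in direction.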

Other observations

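The tests of explanations in the last paragraph of this part were chosen only after the result was seen. So were the genes named here that the rule for named genes does not give. Of the gasdermin C family, known for pore-forming proteins of the colon epithelium, 5 tested members, 1 of them a pseudogene by its name, had lower FPKM in both mutants than in both controls. Gsdmc2 had 162.0 and 170.3 FPKM in the controls and 102.0 and 84.1 FPKM in the mutants (log2 change −0.84, limma adjusted p = 0.447), and Gsdmc3 58.7 and 58.8 against 41.7 and 30.1 FPKM (−0.72, adjusted p = 0.825). These 5 stayed lower after median ratio rescaling, at −0.90 for Gsdmc, −0.65 for Gsdmc2, −0.54 for Gsdmc3, −0.81 for Gsdmc4 and −0.75 for Gsdmcl-ps, and none passed over all genes in limma. Reads can be shared between these similar genes, and the authors' deposited table has Gsdmc in the opposite direction (log2 fold change 2.95), with a control count at 0.126% of the implied fragments, so its value is uncertain. The metallothionein Mt2 had 101.9 and 76.2 FPKM in the controls and 41.7 and 55.8 FPKM in the mutants (−0.86, adjusted p = 0.825), opposite to the higher Mt1. Among hormones, the pancreatic polypeptide gene Ppy had 2.95 and 6.98 FPKM against 21.2 and 8.59 FPKM (1.47, adjusted p = 0.825), and Cck 3.77 and 3.83 against 0.601 and 2.84 FPKM (−1.16, adjusted p = 0.825).

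The controls differed from each other in several lists, among them B cell and clock genes. The B cell surface gene Ms4a1 stood at 21.7 FPKM in control 1 and at 0.796 FPKM in control 2. The clock gene Arntl had 16.2 FPKM in control 1 and 6.45 FPKM in control 2, while the clock output gene Dbp had 6.04 and 30.04 FPKM. In the mutants Arntl had 8.07 and 8.53 FPKM and Dbp 12.2 and 19.9 FPKM. The labels give no time of day.

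Low Tph1, Chga and Chgb were weighed as a pattern of cell loss. Loss of all enteroendocrine cells alike is argued against, since the lowest of 6 hormone genes with at least 10 FPKM in controls had a log2 change of −0.73, against a median of −3.53 for Tph1, Chga and Chgb. That limit leaves out the lower-expressed Insl5 (−2.49, past the threshold), Npy (−1.64) and Cck (−1.16), so a loss of some of these cells is not argued against. Less epithelium is argued against by a lower quartile of −0.30 over 67 absorptive, goblet, tuft and stem genes. Fewer serotonin cells and less RNA of these genes per cell cannot be told apart, since 9 other enterochromaffin list genes, several of them also used by other cells, had a median of −0.40 with quartiles of −0.81 and 0.00. As a hypothesis, loss of Nkx2-2 could lower the serotonin program while Ghrl rises. The controls carried no Cre, so an effect of Villin-Cre itself cannot be told apart from loss of Nkx2-2. Counting serotonin cells in tissue would separate fewer cells from less RNA per cell.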
